A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

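Chromatin immunoprecipitation of budding yeast was read on 12 two-colour Agilent arrays. Per the labels, the Cy5 channel held DNA recovered by a tandem affinity purification (TAP) pull-down and the Cy3 channel held input DNA of the same strain, with no dye swap. Per the labels, cells were grown in rich medium to an optical density of 1.0, crosslinked and lysed, and both DNA samples went through 2 rounds of amplification by in vitro transcription. The labels name IgG-Sepharose in the growth description and Protein G Sepharose in the extraction description, so the bead used for the pull-down is open. Per the submitters' processing notes, slides were read with Agilent Feature Extraction 10.5.1.1 and R 2.12.1 was used. Per the file headers, the signals of each channel are intensity values from which the authors' software had subtracted background, removed spatial trends and scaled the dyes linearly within each array. The deposited mean spot and local background values are intensity as scanned. The deposited value table holds log2 of pull-down over input, and its columns correlate with the same array's log ratio at Pearson r of 0.965 to 0.998. The authors' steps for that table are not stated, and its columns have medians from -0.01 to 0.002 and a median absolute deviation from 0.48 to 0.52.

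The arrays were analysed from the processed channel intensity values. The measure was log2 of Cy5 over Cy3, centred in each array on the median of its 60647 probes that are not controls. Each spot entered on its own, without averaging over spots, and spots flagged as outliers were set to missing. A probe was tested where its input stood well above background on at least 2 of the 3 arrays of every group, which left out 98 probes. Probes that lacked a value on more than 2 arrays were also left out, so that 60546 were tested. Probe coordinates are those of the array design, on build sacCer1 of the Saccharomyces Genome Database. Gene names came from the gene table of the current reference build, which was used for names and neighbours and not for positions.

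Since the coordinates of the arrays and of the gene table are on different builds, probes were assigned to genes by the labels of the array design, a fallback fixed before the data were examined. A label that names a pair of divergent genes marks the interval between them, called a promoter here (1409 labels, 1407 tested). A label that names a single gene is called a coding region here (5617 labels of known genes and 37 unmatched ones, 5635 tested). These single-gene labels also hold upstream probes: 23.9% of probes within 300 bp of the upstream edge had no open reading frame on the sense strand where the gene had no shared promoter label, against 5.5% of the probes farthest inside those labels and 25.5% in the promoter class. A further class was therefore added after the data were seen: the probes within 300 bp of the outermost upstream probe of genes with no shared promoter label, called upstream ends of tandem genes (2822 tested). Transfer RNA genes, small nucleolar RNA genes, centromeres and the ribosomal DNA repeat beyond its TAR1 label are not analysed here.

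Each array contributed the mean log ratio of a region's probes. All 12 arrays entered a model of 4 group means in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 8 residual degrees of freedom before moderation. P values were two-sided and Benjamini-Hochberg adjusted within each comparison and region class, and a call needed an adjusted p under 0.05. Errors beside group means are SD over 3 arrays, and errors beside differences are limma's standard errors (SE). Files were read with data.table, version 1.17.8, and jsonlite, version 2.0.0. The comparisons, the tests, the parameters, 22 gene lists and the rule for named regions were fixed before the data were examined. The rule took, for each tagged strain against wild type, the 12 promoters with the largest higher values and the 4 with the largest lower values, and 8 and 4 coding regions, among called regions with at least 2 probes in which all 3 tagged arrays lay beyond all 3 wild-type arrays. Regions whose gene lacks a standard symbol were passed over, and promoters where both genes lack it, so a promoter with 1 such gene was kept. Dubious reading frames, which the rule also meant to exclude, were passed over only where they lack a symbol. Pairwise comparisons of tagged strains took 5 at each end. The same rule with 8 at the higher end was applied to the added class, and any other region named in the text was chosen after its values were seen.

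Gene lists were tested with limma's camera at a preset correlation of 0.01, over 129 tests in promoters and coding regions together, again with an estimated correlation, and with fry, which asks whether a list moves on balance in one direction and does not compare it with other genes. The added class formed its own family of tests. Feature classes were compared by exact permutation tests on medians per array, two-sided, where 3 arrays against 3 give a p of at least 0.1. The share of ribosomal-protein genes among calls was tested by Fisher's exact test, two-sided. Correlations across promoters were compared with 100 simulated draws in which the tagged strains shared only the wild-type arrays. Bound regions were runs of at least 3 neighbouring probes with gaps of at most 1000 bp, each called higher than wild type with a log2 difference of at least 0.58.

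The model was tested on simulated data with normal noise at the spread limma estimated for each region, with 50 changed regions of each size in a comparison laid out like that of Nhp6A-TAP with wild type. Of promoters given a log2 difference of 0.58, 20% were called, of those given 1, 64%, and of those given 2, 100%, with 7 false calls. For coding regions the shares were 28%, 90% and 100% with 7 false calls, for upstream ends 8%, 54% and 98% with 8 false calls, and for single probes 0%, 6% and 68% with 5 false calls.

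Alternatives were normexp background correction with an offset of 50, the deposited value table, loess within arrays, no centring, centring on the half-sample mode, scaling by the median absolute deviation, no filter on dim probes, a replicate block, a slide block, a fit of only the 2 groups compared, and each array left out in turn. Chosen after seeing the data were a random slide effect, arrays of slide 2 alone, the pull-down channel alone, a loess correction for probe GC content with a span of 0.5, both arrays with dim input left out, coding regions without their upstream 300 bp, and every test of the added class. Also chosen then was a comparison of Nhp6B-TAP and Hmo1-TAP, at regions called in Nhp6A-TAP with 2 wild-type arrays, with the wild-type array kept out of the call. A check of the replicate numbers across strains gave correlations of residuals from -0.27 to 0.22, with 3 of 18 pairs over 0.1, so arrays were not paired by number.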

Results

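Binding of 3 high-mobility-group (HMG) box proteins of budding yeast to DNA was mapped by chromatin immunoprecipitation on tiling arrays. Nhp6A and Nhp6B are closely related, abundant proteins that bend DNA with little sequence preference and work with the histone chaperone FACT, and Hmo1 is an HMG-box protein known from ribosomal DNA and ribosomal-protein genes. The 12 arrays fall into 4 groups of 3, which the labels call biological replicates: an untagged wild-type strain (BY4741) and strains in which Nhp6A, Nhp6B or Hmo1 carries a TAP tag, a protein A based handle for the pull-down. Each array compares the pull-down DNA of 1 culture with its own input, so the wild-type arrays measure what the pull-down recovers with no tagged protein. All values are log2 of pull-down over input, centred on the median probe of the array, so they show enrichment relative to the rest of the genome. The arrays carry 60647 probes, a median of 181 bp apart. Each value rests on 3 arrays per group, and their number limits the precision.

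The median net input signal lay between 1505.1 and 4655.3 on 10 arrays, and was 121.7 on wild type replicate 1 and 258.3 on Hmo1-TAP replicate 3. The median net pull-down signal was 1008.9, 671 and 1034 on the wild-type arrays, 787.5, 401 and 1523.5 for Nhp6A-TAP, 597.8, 764.3 and 631.8 for Nhp6B-TAP, and 489.6, 588.2 and 367.9 for Hmo1-TAP. At least 99.02% of spots stood well above background in every channel, and no spot was saturated. Wild type replicate 1 correlated with the other arrays at r of 0.17 to 0.42 across probes. The log ratios correlated at 0.53 to 0.74 within Nhp6A-TAP, 0.62 to 0.67 within Nhp6B-TAP and 0.53 to 0.71 within Hmo1-TAP, but wild type replicates 2 and 3 correlated with the tagged arrays at 0.48 to 0.79 as well. Slides were inferred from the scan dates in the file headers, and no array position repeats within a slide so defined. By this rule the arrays sat on 3 slides. Wild type replicates 1 and 2 were alone on slide 1, and Hmo1-TAP replicates 2 and 3 alone on slide 3. The rest were on slide 2. A fit with slide as a block, or on slide 2 alone, therefore compares Nhp6A-TAP and Nhp6B-TAP with wild type replicate 3 alone. It compares Hmo1-TAP replicate 1 alone with wild type replicate 3 or with the Nhp6 strains. Such values are given beside the others and do not replicate them. HIS3, LEU2, URA3 and MET17, which BY4741 lacks in whole or in part, had dim input on most arrays at 1 of 4, 6 of 8, 5 of 6 and 6 of 15 of their probes, against 83 of all 60647 probes.

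The comparison of Hmo1-TAP with wild type asks where Hmo1 was recovered with DNA, and values above wild type centred on the promoters of cytosolic ribosomal-protein genes. The region between YGR117C and RPS23A (sacCer1 chromosome 7, 726559 to 726900), which holds the promoter of a small-subunit protein gene, stood at 2.93 ± 0.22 (SD, n = 3) in Hmo1-TAP and -0.92 ± 0.26 in wild type, a difference of 3.86 (SE 0.26, adjusted p = 1.2e-07). The promoter shared by RPS27B and ECM12 (chromosome 8, 148770 to 149053) was higher by 3.63 (SE 0.33), and the one shared by RPS16B and RPL13A (chromosome 4, 307860 to 308334), which serves a protein of each ribosomal subunit, rose from -0.57 ± 0.25 in wild type to 2.57 ± 0.21. YML6/RPS17A and SLX8/RPL23B each rose by 3.36, YBL028C/RPL19B by 3.33, RXT3/RPL31A by 3.05, UGO1/RPL27B by 2.83, RPL33B/DFR1 by 2.61, TEM1/RPS1B by 2.54, TOS4/RPL37A by 2.51 and ROX3/RPL32 by 2.5.

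Of 1407 promoters, 39 were higher in Hmo1-TAP than in wild type and 1 was lower, and 34 of the 39 serve a cytosolic ribosomal-protein gene, of which 69 were tested (Fisher's exact test p = 1.1e-43). The remaining 5 were AAC1/FET3, between genes of a mitochondrial ADP/ATP carrier and an iron oxidase (-0.25 ± 0.17 in Hmo1-TAP and -1.63 ± 0.69 in wild type, a difference of 1.38, adjusted p = 0.025), ARG82/HMO1, SHU2/PET100, TFC6/ESC2 and YBL071C-B/KTI11. The promoter of HMO1 itself (chromosome 4, 811599 to 812030) stood at 0.77 ± 0.29 in Hmo1-TAP and -0.25 ± 0.26 in wild type, a difference of 1.03 (SE 0.26, adjusted p = 0.047). AAC1/FET3 thus lay below the array median in Hmo1-TAP, and it also differed from wild type by 1.94 in Nhp6A-TAP and 1.46 in Nhp6B-TAP. ARG82/HMO1 lost its call without any array except Hmo1-TAP replicate 2 (0.88 without wild type replicate 2). It also lost it with normexp correction and the deposited value table (0.85 each), loess (0.73), no centring (0.97), centring on the half-sample mode (1.04), median absolute deviation scaling (0.94), the replicate block (1.03), the slide block and slide 2 alone (0.96 each), and with both dim-input arrays left out (0.97). This call is weak. AAC1/FET3 lost its call without any array except wild type replicate 3 (1.11 without wild type replicate 1), with normexp correction (0.96), the slide block and slide 2 alone (0.8 each), and with both dim-input arrays left out (1.14). The lower promoter was RTT103/HRQ1, read by 1 probe (-1.94, adjusted p = 0.023). Genes that stand in tandem gave the same picture at their upstream ends, with 20 of 2822 called, all higher, 17 of them at ribosomal-protein genes (Fisher's exact test p = 9e-27): RPL31B rose by 3.39 (SE 0.35, adjusted p = 4.1e-07), RPS6A by 3.21, RPL2A by 3.2, RPS24B by 3.12, RPL34A by 3.07, RPL34B by 3.02, RPL6A by 2.98 and RPL16B by 2.95. Among 5635 coding regions 25 were higher and 0 lower (limma, with 269 at an unadjusted p under 0.05 in either direction), 19 of them of ribosomal-protein genes, led by RPL12A at 2.09 (SE 0.17, adjusted p = 2.7e-05), RPL2A at 1.74, RPS24B and RPS11A at 1.6, RPL42A at 1.5, RPL20B at 1.42 and RPL12B at 1.41. PLS1, which is not on the ribosomal-protein list, stood at 1.72. The other called coding regions off the list were HTC1, YBL071C-B, YGL188C-A, YLR406C-A and YMR242W-A. YLR406C-A shares a run of called probes with the RPL31B label, so a call off the list can hold signal beside a ribosomal-protein gene. How near the other labels lie to such genes was not examined, here or among the promoters and upstream ends. RPS24B lost its coding call without Hmo1-TAP replicate 3 (1.53, adjusted p = 0.066). Without the probes in the upstream 300 bp, 9 coding regions were called, 7 of them of ribosomal-protein genes. With slide as a block, and within slide 2, where 1 Hmo1-TAP array meets 1 wild-type array, 21 promoters and 0 coding regions were called, and with the block 11 upstream ends. The median difference over the 39 promoters was 2.14 without the block and 2.2 with it, while its median SE went from 0.26 to 0.49.

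**Figure D1:**
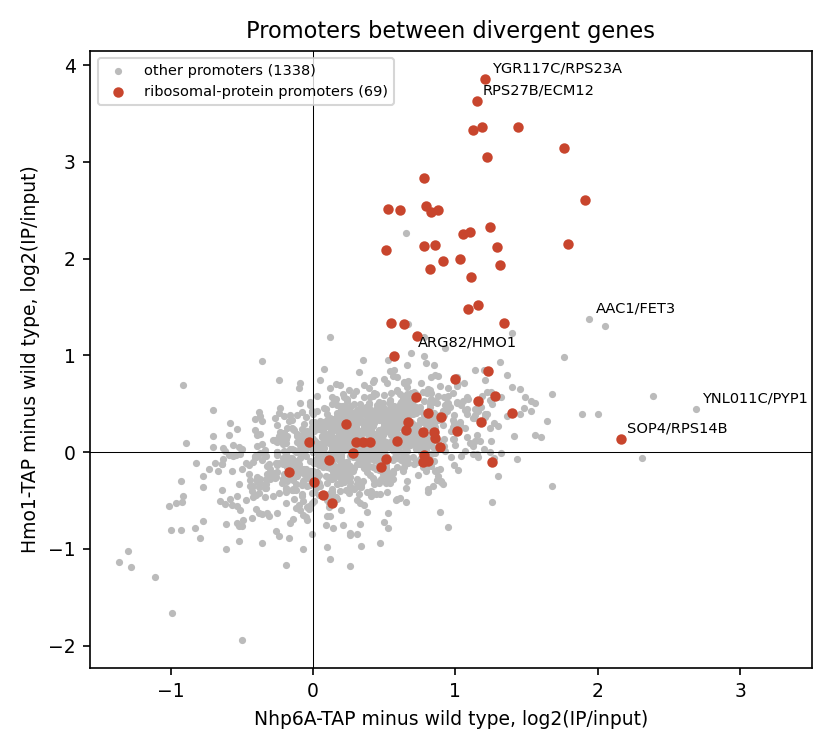
Each point is a promoter between divergent genes, with its log2 difference from wild type in Nhp6A-TAP on the x axis and in Hmo1-TAP on the y axis, each a mean of 3 arrays minus a mean of 3. The 69 ribosomal-protein promoters (red) spread up to 3.86 on the Hmo1-TAP axis at YGR117C/RPS23A, while YNL011C/PYP1 lies farthest along the Nhp6A-TAP axis at 2.69.

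Cytosolic ribosomal-protein promoters as a list had a median difference of 0.84 and a mean of 1.2 in Hmo1-TAP, with 34 of 69 called higher, 36 when adjusted over the list alone, and 0 lower. Their wild-type median was -0.3 ± 0.12. Camera placed the list above other promoters (adjusted p = 5.9e-35, and adjusted p = 0.044 with an estimated correlation). At the upstream ends of tandem ribosomal-protein genes the median was 0.61 and the mean 0.99, with 17 of 63 called and 23 when adjusted over the list alone (adjusted p = 5.9e-28, and adjusted p = 0.0058 with an estimated correlation). In their coding regions it was 0.27, with 19 of 134 called and 29 when adjusted over the list alone (adjusted p = 1.3e-23, and adjusted p = 0.02 with an estimated correlation). Hmo1-TAP replicate 1 against wild type replicate 3, the only arrays of these groups on the same slide, gave medians of 0.96, 0.71 and 0.31 for promoters, upstream ends and coding regions. With both dim-input arrays left out these medians were 0.98, 0.39 and 0.23. The list did not move evenly: of 132 ribosomal-protein promoters and upstream ends, 44 differed from wild type by more than 1.5, 28 by 0.5 to 1.5 and 60 by less than 0.5. No other list was called by camera in Hmo1-TAP. Mitochondrial ribosomal-protein promoters had a median of -0.01 with 0 of 35 called, glycolysis promoters 0.05 with 0 of 10 called, and core histone promoters 0.02 with 0 of 6 called by limma, which gave 118 promoters of all kinds an unadjusted p under 0.05.

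**Figure D2:**
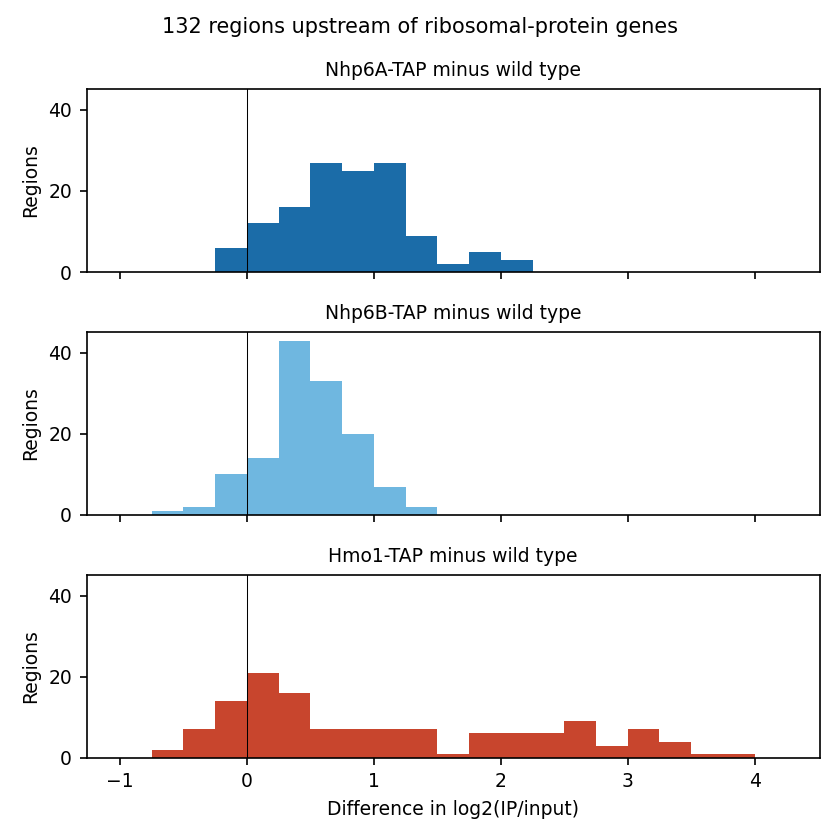
Histograms of the log2 difference from wild type at 132 promoters and upstream ends of cytosolic ribosomal-protein genes, with the number of regions on the y axis and 1 panel per tagged strain (3 arrays each). The Hmo1-TAP values spread from below 0 to above 3, with 60 regions under 0.5 and 44 over 1.5.

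The comparison of Nhp6A-TAP with wild type asks where Nhp6A was recovered, and values above wild type reached promoters of many kinds. Whether they reflect binding of Nhp6A remains a hypothesis, since pull-down background and slide are not excluded. The largest difference lay between YNL011C and PYP1 (chromosome 14, 613224 to 613579), at 1.83 ± 0.12 in Nhp6A-TAP and -0.86 ± 0.52 in wild type, a difference of 2.69 (SE 0.33, adjusted p = 0.00027). The promoter shared by UTP4, a gene of ribosome assembly, and YCG1, a condensin gene (chromosome 4, 1116847 to 1117086), rose by 2.39 (adjusted p = 0.00062), and SOP4/RPS14B (chromosome 10, 73391 to 73761) rose from -0.38 ± 0.3 to 1.78 ± 0.16, a difference of 2.16 (SE 0.26, adjusted p = 0.00027). AGE1/YDR524W-C rose by 2.31, RPC40/DBF20, with the gene of a subunit common to RNA polymerases I and III, by 2, AAC1/FET3 by 1.94, RPL33B/DFR1 by 1.91, RPS22A/RPL39 by 1.79, YDR524C-B/SNA2 and RPS16B/RPL13A by 1.76, and SPO74/SUA5 and COG4/ISR1 by 1.68. Upstream ends of tandem genes included SED1, a cell wall protein gene (chromosome 4, 599717 to 599968), at 1.27 ± 0.29 in Nhp6A-TAP and -1.19 ± 0.16 in wild type, a difference of 2.46 (SE 0.31, adjusted p = 6.5e-05). FDO1 rose by 2.38, TEF1, which encodes translation elongation factor 1A, by 2.36, FOX2 by 2.22, PPH21 by 2.17, MNN4 and VPS53 by 2.16 and VHR2 by 2.14.

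In all, 121 of 1407 promoters were higher in Nhp6A-TAP and 2 lower, 166 of 2822 upstream ends were higher and 3 lower, and 90 of 5635 coding regions were higher and 8 lower. Centring on the half-sample mode called 53 promoters, 73 upstream ends and 29 coding regions, and the pull-down channel alone 275, 249 and 192. The median over all promoters was itself 0.34, so most called promoters, with a median of 1.17, stood above a broad shift. The lower promoters were MED11/FOL3 (-0.96, adjusted p = 0.045) and PML1/MEU1 (-1.3, 1 probe), and the lower upstream ends were PRP45 (-1.26), PRM7 (-1.32) and YGR226C (-1.41). Coding regions higher in Nhp6A-TAP included UTR5 (2.27), HTC1 (2.24), SPC25 (2.16), SHR5 (1.97), TIF1, a gene of translation initiation factor 4A (1.46, adjusted p = 0.0022), PHO4 (1.43), YCH1 (1.41) and CCW12, which encodes a cell wall protein (1 ± 0.07 against -0.64 ± 0.47 in wild type, adjusted p = 0.0092). SNZ1 (-1.13, adjusted p = 0.017), UMP1 (-1.02), ACF4 (-1) and ACA1 (-0.95) were lower, along with NIT2, PMA2, SEF1 and UIP5. Without their upstream 300 bp 39 coding regions were called. With loess 135 coding regions were higher and 87 lower, with normexp correction 131 and 90, and 88 and 20 from the deposited value table. Centring on the half-sample mode gave 28 and 1, so the share of lower calls in coding regions depends on the processing.

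The input channel alone, which holds no pull-down DNA, differed between Nhp6A-TAP and wild type at 92 of 1407 promoters (56 higher, 36 lower), 1102 of 5635 coding regions (602 and 500) and 171 of 2822 upstream ends (87 and 84). Input profiles correlated at 0.93 or more among the Nhp6A-TAP arrays and at 0.78 to 0.87 between these and wild type replicates 2 and 3. They did not group by strain alone. The Nhp6A-TAP inputs correlated with Hmo1-TAP replicate 2 at 0.93 to 0.96 and with Nhp6B-TAP replicate 3 at 0.86 to 0.93. Wild type replicates 2 and 3 correlated at 0.94 to 0.96 with Nhp6B-TAP replicates 1 and 2 and Hmo1-TAP replicate 1. A shared preparation behind these groups was not tested and cannot be told apart from strain in this comparison. At the 121 called promoters, SOP4/RPS14B among them, the median input difference was -0.05 and that of the pull-down channel 1.12. At the 90 coding regions called higher these medians were -0.19 and 0.93, and at the 166 upstream ends -0.12 and 1.2.

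These counts rest on single arrays in part. The promoter count of 123 became 78 without wild type replicate 1, 70 without wild type replicate 3, 75 without Nhp6A-TAP replicate 1 and 65 without Nhp6A-TAP replicate 3. The upstream-end count of 169 became 91, 94, 91 and 79 without the same arrays, and the coding count of 98 became 31, 48, 56 and 26, and 57 without Nhp6A-TAP replicate 2. MED11/FOL3, at -0.96, lost its call without any 1 of the 6 arrays (values from -0.79 without Nhp6A-TAP replicate 2 to -1.1 without wild type replicate 3), as did PRM7 (-1.1 without Nhp6A-TAP replicate 2 to -1.46 without Nhp6A-TAP replicate 1). ACA1 and ACF4 lost theirs without any array except Nhp6A-TAP replicate 1, reaching -0.79 and -0.88, and UMP1 likewise, reaching -0.89. SNZ1 lost its call without wild type replicate 1 (-0.95) and Nhp6A-TAP replicates 2 (-1) and 3 (-1.08). SPC25 and SHR5 lost theirs without any array except wild type replicate 2, and without wild type replicate 1 stood at 1.44 and 1.35. PHO4 lost its call without Nhp6A-TAP replicate 1 (1.32) or 3 (1.46), YCH1 without wild type replicate 1 (1.31) or Nhp6A-TAP replicate 3 (1.38), and SPO74/SUA5 without Nhp6A-TAP replicate 2 (1.4) or 3 (1.64). With slide as a block 5 promoters were called (YNL011C/PYP1, SOP4/RPS14B, RPC40/DBF20, RPS22A/RPL39 and RPS16B/RPL13A), along with 3 upstream ends and 0 coding regions. Within slide 2 alone 11 promoters, 40 upstream ends and 2 coding regions were called. The median difference at the 121 promoters was 1.17 with and without the block, and its median SE went from 0.27 to 0.39.

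Ribosomal-protein promoters stood out among those of Nhp6A-TAP too, with a median of 0.85, 30 of 69 called higher and 0 lower, 49 higher when adjusted over the list alone, and a slide-blocked and within-slide-2 median of 0.83. Camera placed the list above other promoters (adjusted p = 2e-12), a call that was lost at adjusted p = 0.36 with an estimated correlation. Fry, which does not compare with other promoters, gave an adjusted p of 0.0016. At upstream ends the median was 0.67 with 17 of 63 called and 25 when adjusted over the list alone (adjusted p = 8.6e-07 by camera, and adjusted p = 0.22 with an estimated correlation), and 0.66 with the slide block. In coding regions it was 0.39 with 13 of 134 called and 45 when adjusted over the list alone (adjusted p = 1.5e-22, and adjusted p = 0.02 with an estimated correlation), and 0.35 with the slide block. Of the 121 higher promoters 30 serve a ribosomal-protein gene (Fisher's exact test p = 6.8e-16), as do 17 of the 166 upstream ends (p = 5.1e-08 by the same exact test).

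Glycolytic and fermentation genes, which are among the most transcribed in glucose, were also called in Nhp6A-TAP at upstream ends and in coding regions. Upstream of 12 tandem members the median was 0.89, with 5 called higher and 7 when adjusted over the list alone, among them GPM1 (1.78, adjusted p = 0.002), TPI1 (1.49), ENO2 (1.4) and PDC1 (1.38). Camera called the list (adjusted p = 0.00033, and adjusted p = 0.32 with an estimated correlation), and the slide-blocked median was 0.94, while loess gave 0.44 and no call (adjusted p = 0.64). In coding regions the list went from -0.44 ± 0.16 in wild type to -0.1 ± 0.09 in Nhp6A-TAP and so stayed below the array median. The median difference there was 0.27 with 4 of 22 called higher, 8 higher and 1 lower when adjusted over the list alone (adjusted p = 0.00017, and adjusted p = 0.89 with an estimated correlation), but 0.13 and no call with the slide block (adjusted p = 0.073) or within slide 2 (adjusted p = 0.12). The promoter of the pyruvate kinase gene in CYC3/CDC19 rose by 1.4 (adjusted p = 0.0044), ADP1/PGK1 by 0.91 and TDH2/MET3 by 0.86, 3 of 10 glycolysis promoters, or 6 when adjusted over the list alone.

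Core histone genes gave a median of 0.53 over 10 coding regions in Nhp6A-TAP, with HHF2, a histone H4 gene, higher by 1.52 (adjusted p = 0.035) and 4 called when adjusted over the list alone. HHF2 lost its call without any array except wild type replicate 3 (1.31 without Nhp6A-TAP replicate 2) and stood at 1.07 with the slide block. Camera called this list (adjusted p = 0.0014, and adjusted p = 0.21 with an estimated correlation), and the slide block ended the call at 0.31 (adjusted p = 0.073). Highly transcribed cell wall and plasma membrane genes had a median of 0.6 at 21 upstream ends, where 6 rose (7 when adjusted over the list alone), including SED1, CIS3 (1.54), SUN4 (1.46) and UTH1 (1.46), with adjusted p = 0.012 by camera and adjusted p = 0.85 with an estimated correlation. That call was lost without Nhp6A-TAP replicate 1 (0.41, adjusted p = 0.1) and with loess (0.35, adjusted p = 0.55), and the slide-blocked median was 0.51. Their coding regions had a median of 0.28, with CCW12, SED1 (0.96) and CIS3 (0.83) called among 27 and 3 when adjusted over the list alone (adjusted p = 4e-04, adjusted p = 0.89 with an estimated correlation, and 0.12 with the slide block). Among 13 G1 cyclin and cell-cycle box genes, CLN3 (1.72, adjusted p = 0.0011), PCL1 (1.54, from -1.58 in wild type to -0.04) and CLN1 (1.22) rose at their upstream ends, and 4 did when adjusted over the list alone. The list median was 0.64 (adjusted p = 0.029 by camera, and adjusted p = 0.85 with an estimated correlation), its call was lost without wild type replicate 2 (0.75, adjusted p = 0.18), wild type replicate 3 (0.67, adjusted p = 0.063) or Nhp6A-TAP replicate 1 (0.72, adjusted p = 0.1), and the slide-blocked median was 0.73.

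The comparison of Nhp6B-TAP with wild type asks the same of the paralog. None of 1407 promoters passed in limma, a count of 0 with 220 at an unadjusted p under 0.05, although UTP4/YCG1 stood at 1.61 (adjusted p = 0.074), AAC1/FET3 at 1.46 (adjusted p = 0.074), SOP4/RPS14B at 1.43 (adjusted p = 0.067) and COG4/ISR1 at 1.07 (adjusted p = 0.074). The promoter count was 6 from the deposited value table, 7 with median absolute deviation scaling, 8 with a random slide effect and 46 in the pull-down channel alone. It stayed at 0 with normexp correction, loess and centring on the half-sample mode. Of 2822 upstream ends 17 were higher and 0 lower (limma, 252 at an unadjusted p under 0.05). They included OAC1, a mitochondrial oxaloacetate carrier gene, at 2.16, PRB1, which encodes vacuolar protease B, at 2.04, MNN4 at 1.93, VPS53 at 1.89, ERG11 of ergosterol synthesis at 1.85, ZEO1 at 1.82, VHR2 at 1.68 and TEF1 at 1.66, along with PYC1 at 1.61, SED1 at 1.59, FAS1 at 1.57, the G1 cyclin gene CLN3 at 1.55 and RPL34A at 1.49. All 17 were also called in Nhp6A-TAP, a comparison that shares its wild-type arrays with this one. Of the coding regions 1 was higher, HTC1 (chromosome 16, 425351 to 425738), at -0.33 ± 0.36 in Nhp6B-TAP and -2.15 ± 0.36 in wild type, a difference of 1.82 (SE 0.25, adjusted p = 0.021). HTC1 was also called in Nhp6A-TAP (0.09 ± 0.4, a difference of 2.24) and in Hmo1-TAP (-0.88 ± 0.32, a difference of 1.27, adjusted p = 0.039). All 3 calls share its low wild-type value. The upstream-end count of 17 became 0 without Nhp6B-TAP replicate 2, 5 without wild type replicate 1 and 9 without Nhp6B-TAP replicate 1, so each named upstream end lost its call without at least Nhp6B-TAP replicate 2. VPS53 (1.61 without wild type replicate 1), ERG11 (1.67 without wild type replicate 2), ZEO1 (1.61 without wild type replicate 1) and TEF1 (1.13 without wild type replicate 1) lost theirs without other arrays as well. HTC1 lost its call without wild type replicate 1 (1.64) or 2 (1.84) or Nhp6B-TAP replicate 2 (1.63) or 3 (1.84). With slide as a block, and within slide 2, limma called 0 upstream ends, 0 promoters and 0 coding regions.

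Ribosomal-protein promoters had a median of 0.49 in Nhp6B-TAP, with 0 of 69 called by limma and 11 when adjusted over the list alone. Camera called the list (adjusted p = 2.5e-07, lost at adjusted p = 0.77 with an estimated correlation), and the slide-blocked and within-slide-2 median was 0.51. Their upstream ends had a median of 0.46 with 1 of 63 called and 3 when adjusted over the list alone (adjusted p = 4.6e-05, and adjusted p = 0.29 with an estimated correlation), and their coding regions 0.17 (-0.07 ± 0.02 in Nhp6B-TAP itself) with 0 of 134 called in either way (adjusted p = 5.3e-09, and adjusted p = 0.18 with an estimated correlation). The slide-blocked medians were 0.48 and 0.14. Glycolysis genes had a median of 0.93 at 12 upstream ends, with 0 called and 7 when adjusted over the list alone (adjusted p = 6.9e-06, adjusted p = 0.22 with an estimated correlation, slide-blocked median 0.9), and of 0.32 in 22 coding regions (-0.08 ± 0.21 in Nhp6B-TAP itself) with 4 called when adjusted over the list alone (adjusted p = 5.9e-08, adjusted p = 0.77 with an estimated correlation, slide-blocked median 0.12). Cell wall genes were called at upstream ends with a median of 0.5 and 2 of 21 members (adjusted p = 0.00079, adjusted p = 0.85 with an estimated correlation, slide-blocked median 0.35) and in coding regions with 0.25 (adjusted p = 1.8e-06, adjusted p = 0.77 with an estimated correlation, slide-blocked median 0.13). Core histone coding regions had a median of 0.35 (adjusted p = 0.0038, and adjusted p = 0.25 with an estimated correlation), a call lost without wild type replicate 2 (0.32, adjusted p = 0.1), without Nhp6B-TAP replicate 1 (0.24, adjusted p = 0.082) and with the slide block (0.13, adjusted p = 0.28).

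Nhp6A-TAP and Nhp6B-TAP were compared directly, since the paralogs carry nearly the same DNA-binding domain. Of the 121 promoters called higher in Nhp6A-TAP, such as YNL011C/PYP1 and SOP4/RPS14B, 121 lay above wild type in Nhp6B-TAP, with medians of 1.17 in Nhp6A-TAP and 0.7 in Nhp6B-TAP. The shared wild-type arrays alone would tend to put such promoters above wild type in any strain, so the calls were repeated with 2 wild-type arrays. Nhp6B-TAP was then measured against the array kept out. Without wild type replicates 1, 2 and 3 the Nhp6B-TAP medians were 0.82, 0.37 and 0.72, above 0 at 75 of 78, 126 of 157 and 67 of 69 promoters, where all 1407 promoters had medians of 0.38, 0.1 and 0.25. Hmo1-TAP at the same promoters had medians of 0.5, 0.09 and 0.36, above 0 at 55 of 78, 96 of 157 and 61 of 69, where all promoters had 0.27, -0.05 and 0.13. Part of the excess was thus not particular to the paralog. With all arrays, the values were higher in Nhp6A-TAP at 120 of the 121, by a median of 0.5 with a median 95% half-width of 0.56. Over all 1407 promoters the median difference between these strains was 0.1. At the 166 upstream ends the medians were 1.37 and 0.87, and 164 lay above wild type in Nhp6B-TAP. In the 90 coding regions they were 1.05 and 0.63. These regions were chosen for their Nhp6A-TAP values. In limma 0 promoters differed between the 2 strains, with 82 at an unadjusted p under 0.05, 0 upstream ends with 170, and 0 coding regions with 401. Leaving out Nhp6A-TAP replicate 1 gave 1 promoter. All arrays of both strains sat on slide 2. Across 1407 promoters the differences from wild type correlated at Pearson r of 0.73 (Spearman 0.71) between Nhp6A-TAP and Nhp6B-TAP, 0.49 (0.49) between Nhp6A-TAP and Hmo1-TAP, and 0.52 (0.55) between Nhp6B-TAP and Hmo1-TAP, while simulated strains that share only the wild-type arrays gave 0.5. With loess the correlations were 0.66, 0.57 and 0.64 in the same order, so the margin of the Nhp6 pair over the others depends on the processing. Without loess, the covariances were 0.13, 0.122 and 0.098 against a simulated 0.05. Promoters are not independent replicates, and the simulation shares the wild-type arrays with the noise that limma estimated.

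Hmo1-TAP and Nhp6A-TAP differed directly at 84 promoters, 24 higher in Hmo1-TAP and 60 lower, and the higher ones with the largest differences were ribosomal-protein promoters. YGR117C/RPS23A was higher in Hmo1-TAP than in Nhp6A-TAP by 2.65, RPS27B/ECM12 by 2.48, YBL028C/RPL19B by 2.21, SLX8/RPL23B by 2.17 and UGO1/RPL27B by 2.06. The largest lower differences were at AGE1/YDR524W-C (-2.37), YNL011C/PYP1 (-2.24), SPO74/SUA5 (-2.03), SOP4/RPS14B (-2.02) and UTP4/YCG1 (-1.81), so the promoter of a ribosomal-protein gene, RPS14B, stood among them. The count was 46 without Nhp6A-TAP replicate 3 or Hmo1-TAP replicate 3, and 1 with slide as a block, which was YGR117C/RPS23A, or 20 within slide 2, both with Hmo1-TAP replicate 1 alone. With centring on the half-sample mode 18 were higher and 19 lower, and within slide 2 12 and 8. Against Nhp6B-TAP, Hmo1-TAP was higher at 26 promoters and lower at 5. YGR117C/RPS23A was higher by 3.16, RPS27B/ECM12 by 2.8, YBL028C/RPL19B by 2.72, YML6/RPS17A by 2.67 and RXT3/RPL31A by 2.33. The slide block and slide 2 alone, which leave only Hmo1-TAP replicate 1, each called 15 promoters. SOP4/RPS14B (-1.29), GYP8/STE2 (-1.16), CMD1/ALG1 (-1.01), APM2/MCO14 (-1.26, 1 probe) and CDC10/MRPL32 (-1.37, 1 probe) were lower. SOP4/RPS14B lost this call without Nhp6B-TAP replicate 2 (-1.14) or 3 (-1.2), GYP8/STE2 without any array except Hmo1-TAP replicate 2 (-0.91 without Hmo1-TAP replicate 3), and CMD1/ALG1 without any except Hmo1-TAP replicate 1 (-0.83 without Hmo1-TAP replicate 3). With loess 13 were higher and 0 lower, and with normexp correction 25 and 1.

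Calls of Hmo1-TAP and Nhp6A-TAP overlapped at 20 promoters, among them AAC1/FET3, RPS16B/RPL13A and RPL33B/DFR1, at 8 upstream ends and at 5 coding regions. Among the 132 ribosomal-protein promoters and upstream ends, 27 were called in both strains, 24 in Hmo1-TAP alone, 20 in Nhp6A-TAP alone and 61 in neither. The median Nhp6A-TAP difference was 1.05 where Hmo1-TAP was called and 0.59 where it was not, and that of Nhp6B-TAP was 0.61 and 0.4. The comparisons share their wild-type arrays, which alone raise such an overlap, and it was not tested against a value that allows for them.

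By position, values in all 3 tagged strains were largest at the upstream ends of genes. They were largest in Nhp6A-TAP. Over the 4554 probes between divergent genes, such as GAL10/GAL1, the median was 0.41 ± 0.08 in Nhp6A-TAP, 0.28 ± 0.03 in Nhp6B-TAP, 0.13 ± 0.04 in Hmo1-TAP and 0 ± 0.08 in wild type (exact permutation p = 0.1 for each, the smallest that 3 arrays against 3 can give). Probes at the upstream ends of tandem genes differed from wild type by 0.32 in Nhp6A-TAP, 0.18 in Nhp6B-TAP and 0.1 in Hmo1-TAP (exact permutation p = 0.1, 0.1 and 0.3). Probes of single-gene labels differed from wild type by -0.03, -0.02 and -0.01, and probes within 15 kb of the ends of chromosomes by -0.01, -0.03 and 0. From the upstream edge of tandem genes inwards, Nhp6A-TAP went from 0.43 ± 0.12 within 150 bp to 0.2 at 300 to 450 bp and 0.01 at 600 to 900 bp, Nhp6B-TAP from 0.29 ± 0.08 to 0.14 and 0.02, Hmo1-TAP from 0.23 ± 0.1 to 0.1 and 0.04, and wild type from 0.13 ± 0.15 to 0.05 and 0.03. Mitochondrial probes stood at -2.82 ± 0.39 in wild type and differed by 0.14, 0.12 and 0.66 (exact permutation p = 0.8, 0.7 and 0.3). TAR1, within the ribosomal DNA and read by 3 probes, differed by 0.52, 0.27 and 0.35 (exact permutation p = 0.1, 0.3 and 0.4).

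**Figure D3:**
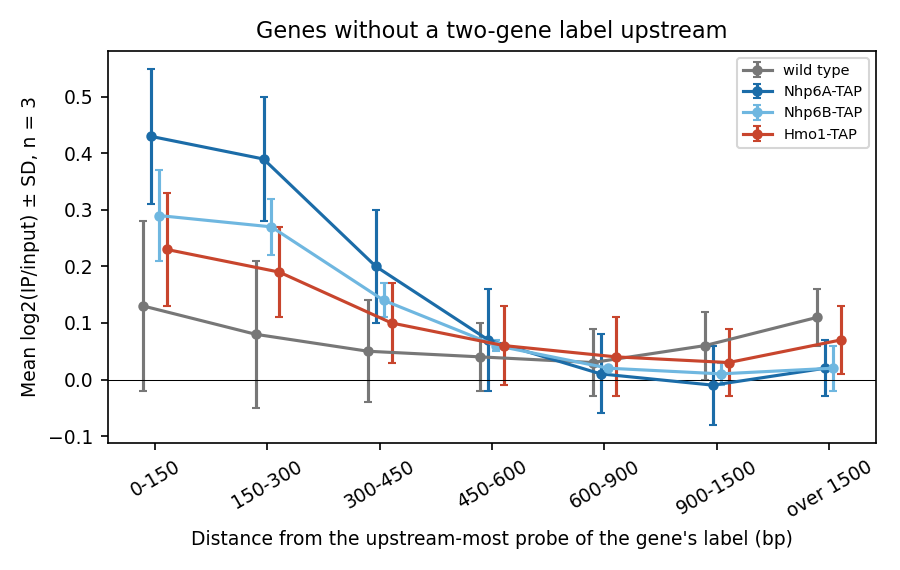
Mean log2 of pull-down over input (y axis) by distance in bp from the upstream edge of genes with no shared promoter label (x axis), with a line per strain that joins the means of 3 arrays and bars of 1 SD. Nhp6A-TAP stands at 0.43 and Nhp6B-TAP at 0.29 within 150 bp, against 0.13 in wild type, and all strains lie within 0.07 of 0 at 600 to 900 bp.

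Runs of called probes gave 30 bound regions for Hmo1-TAP, with a median length of 393.5 bp, and all 30 carry the label of a ribosomal-protein gene. For Nhp6A-TAP there were 10, with a median length of 414 bp, at CYC3/CDC19 (chromosome 1, 71002 to 71522), SED1, PMP3, RPI1/RHO3, SOP4/RPS14B, FAS1, YLR412C-A, SUN4, YNL011C/PYP1 and TYE7, and 1 of them, SOP4/RPS14B, holds a ribosomal-protein gene. None was shared, and Nhp6B-TAP had 0, with 7 single probes called by limma and 3307 at an unadjusted p under 0.05. The 10 Nhp6A-TAP regions became 1 without wild type replicate 1, 3 without wild type replicate 3, 0 without Nhp6A-TAP replicate 1, 3 without replicate 2 and 0 without replicate 3, while the 30 Hmo1-TAP regions became 18 without wild type replicate 3 and 17 without Hmo1-TAP replicate 2. Single probes called were 342 higher and 13 lower for Nhp6A-TAP, and 149 and 2 for Hmo1-TAP, of 60546. For Nhp6A-TAP loess gave 245 and 115 and normexp correction 684 and 408. The 355 probes of Nhp6A-TAP became 156 and 208 without wild type replicates 1 and 3, and 128, 200 and 141 without Nhp6A-TAP replicates 1, 2 and 3, and the 7 of Nhp6B-TAP became 1 without wild type replicate 1, 1 without Nhp6B-TAP replicate 2 and 3 without Nhp6B-TAP replicate 3.

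**Figure D4:**
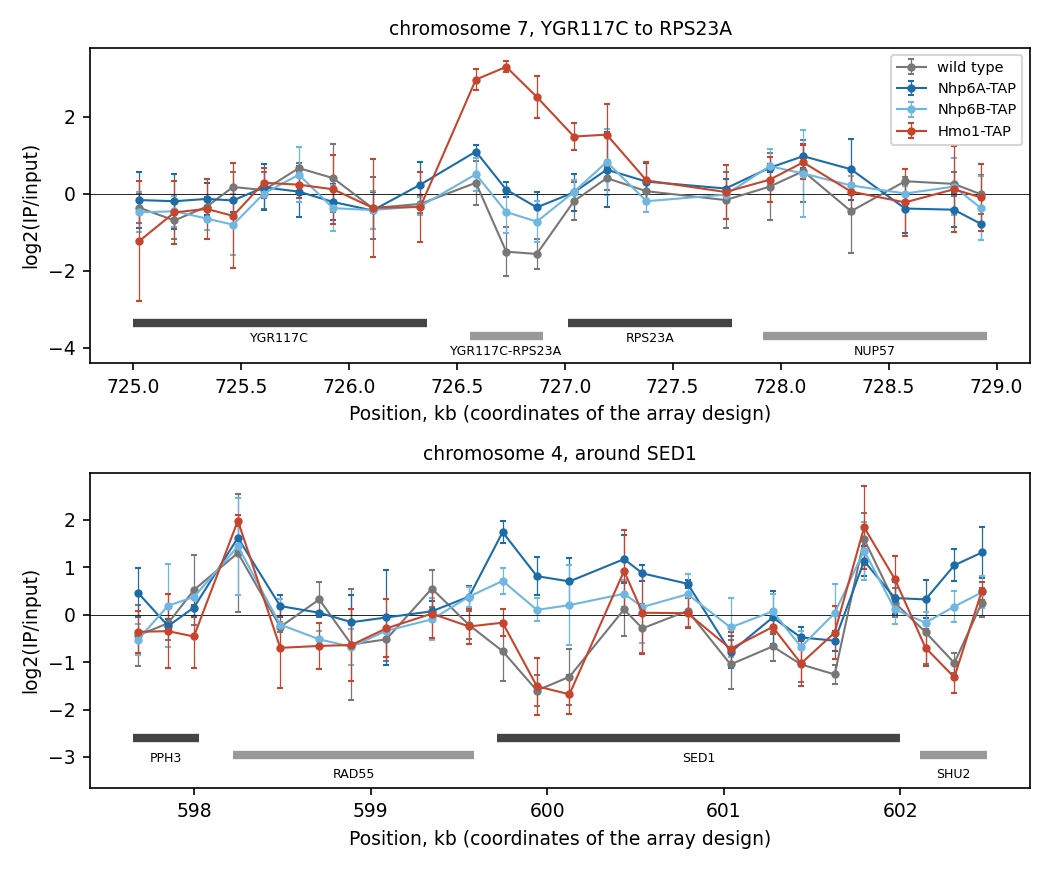
Maps around YGR117C/RPS23A (top) and SED1 (bottom), with position in kb in the coordinates of the array design on the x axis and log2 of pull-down over input per probe on the y axis, as mean and SD of 3 arrays per strain over bars that mark the array's gene labels. Between YGR117C and RPS23A Hmo1-TAP stands highest (region mean 2.93, against -0.92 in wild type), and at the upstream end of SED1 Nhp6A-TAP does (1.27, against -1.19 in wild type).

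The genes fixed in advance for their known links to these proteins gave mostly small values where a region was tested. SNR6, also on that list, had no region among those tested and so has no value here. At NHP6A/SMK1 the promoter differences in Nhp6A-TAP, Nhp6B-TAP and Hmo1-TAP were 0.54, 0.74 and 0.1. At CHA1/VAC17 they were 0.63, 0.51 and 0.55, at PHO5/PBY1 0.43, 0.36 and 0.13, at GAL10/GAL1 0.12, 0.17 and -0.01, and at ARG82/HMO1 0.69, 0.48 and 1.03, of which only the last passed. HO, which has no shared promoter label, gave 0.32, -0.19 and 0.2 at its upstream end, and NHP6B 0.47, 0.51 and 0.01. CUP1-1, read by 1 probe with a wild-type SD of 2.48, gave 1.71, 1.36 and 1.15 and did not pass.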

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

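Chosen only after the result was seen were the tests of the input profile, of the pull-down background, of the spread of the arrays and of the error at uncalled regions, and every split of the upstream ends of tandem genes. Effects of Hmo1-TAP and Nhp6A-TAP against the same wild type differed at 84 promoters in the direct test, 24 higher in Hmo1-TAP, led by YGR117C/RPS23A, and 60 lower, led by AGE1/YDR524W-C. Effects of Hmo1-TAP and Nhp6B-TAP differed at 31 promoters, 26 higher in Hmo1-TAP and 5 lower, among them SOP4/RPS14B.

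Nhp6A-TAP stood above wild type at 121 promoters, by a median of 1.17. A difference in the input DNA of the Nhp6A-TAP cultures would have to vanish from the pull-down channel. There the same promoters still differed by a median of 1.12 (quartiles 0.83 and 1.34), while the input channel differed by -0.05 (quartiles -0.35 and 0.14). These values argue against input as the main source at these promoters, and cover no other class. They do not address a difference in preparation that touches both channels, which was not tested. A stronger version of the pull-down background would need these promoters to be enriched in wild type. In wild type replicate 3, which was not used to pick them, 69 promoters called with the other wild-type arrays had a median of -0.38 (quartiles -0.59 and -0.16). With replicate 1 kept out the median in it was -0.38 at 78 promoters, and with replicate 2 kept out 0.03 at 157. Calls against wild type favour promoters low in wild type, and wild type replicates 2 and 3 correlated at 0.79. A low value in the array kept out was thus partly built in, so these values do not exclude that background. The slide stays open: with slide as a block the median was 1.17 (quartiles 0.97 and 1.35), yet the bound set in advance for that value was wrong, because by the layout the blocked value rests on wild type replicate 3 alone, so slide and strain cannot be told apart beyond that array. Binding of Nhp6A at these promoters remains a hypothesis.

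Nhp6B-TAP lay below Nhp6A-TAP at 120 of those 121 promoters, by a median of 0.5, although none passed the direct test. Picking promoters by their Nhp6A-TAP values may inflate that gap, but when each Nhp6A-TAP array in turn was kept out of the picking, it still stood above the Nhp6B-TAP mean by medians of 0.27 at the lowest and 0.59 at the highest, above 0 at 78 of 114, 70 of 73 and 61 of 65 promoters. Over all 1407 promoters, with all arrays, Nhp6A-TAP exceeded Nhp6B-TAP by a median of 0.1, so part of the gap is not particular to the picked promoters. Unequal spread of the log ratios would close the gap at the 121 promoters after scaling, and it was then 0.47. Chance with 3 arrays against 3 is not excluded, since the median gap of 0.5 lay under the median half-width of its confidence intervals, 0.56. The 121 promoters were read on the same arrays and are not independent, so the 120 of 121 does not settle this. If the gap is real, a lower amount or recovery of the tagged Nhp6B, which was not tested, or less binding stays open.

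Hmo1-TAP differed from wild type by less than 0.5 at 60 of 132 ribosomal-protein regions, while 44 differed by more than 1.5. Larger error at the 81 uncalled regions could hide differences like the median of 2.48 at the called ones only with an SE of 0.54 or more, but their median SE was 0.31 (quartiles 0.29 and 0.34), against 0.29 at the called regions. A narrow site averaged away within a region would show in its best probe, whose median was 0.66 at the uncalled regions, with 4 of 81 over 1.5. That lies above the 0.46 of random regions of the same size and their range of 0.37 to 0.56, and far below the 3.93 of the called regions. Both tests took the 81 uncalled regions and not the 60 under 0.5, and neither can see a site outside a region's probes. The upstream end of RPL42A differed by 0.44, yet a run of 3 called probes under its label had a mean of 3.15. Unequal binding of Hmo1 among these genes thus stays a hypothesis found on the same arrays, and sites outside the regions are not excluded.

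For each count, the 6 arrays of a comparison were also split into 3 and 3 in every other way. With 10 splits the share as large as the real one cannot fall under 0.05. At promoters the real count and the highest other were 123 and 0 for Nhp6A-TAP, 40 and 0 for Hmo1-TAP, 84 and 1 for Hmo1-TAP against Nhp6A-TAP, and 31 and 0 for Hmo1-TAP against Nhp6B-TAP. In coding regions they were 98 and 0 for Nhp6A-TAP, 1 and 0 for Nhp6B-TAP and 25 and 0 for Hmo1-TAP, at upstream ends 169 and 0, 17 and 0, and 20 and 0, and at probes 355 and 0, 7 and 0, and 151 and 75. In each of these 1 of 10 splits, the real one, gave as many. The split with 75 probes put Hmo1-TAP replicates 1 and 2 and wild type replicate 2 against Hmo1-TAP replicate 3 and wild type replicates 1 and 3, so that both arrays with dim input, wild type replicate 1 and Hmo1-TAP replicate 3, were on the same side. At promoters of Nhp6B-TAP against wild type and of Nhp6A-TAP against Nhp6B-TAP the real count was 0 and the highest other 0, so all 10 of 10 splits gave as many.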

How the results depend on the processing

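Chosen after seeing the data were a random slide effect, slide 2 alone, the pull-down channel alone, the GC correction, both dim-input arrays left out, coding regions without their upstream 300 bp, the wild-type array kept out of the Nhp6A-TAP calls in turn, and all tests of upstream ends. For results that answer a comparison, 404 of 550 alternative values stayed on the same side or within 1.5 times, 141 moved and 5 lost a call. Only the ribosomal-protein list shifts among them could be marked as lost or reversed, and none of these reversed. Counts and correlations could not be. The split of calls did change: for Hmo1-TAP against Nhp6A-TAP, 24 higher and 60 lower promoters became 18 and 19 with centring on the half-sample mode. Of 1843 values of named regions 1563 kept their call and direction and 280 kept the direction alone. Of 165 values of called lists 130 kept the call and 35 did not, of 162 feature-class medians 153 stayed within 1 SD and 9 moved, and of 98 wild-type list values 84 stayed and 14 moved. The cause of these changes was not tested, except that fewer arrays raise the error. Slides 1 and 3 each hold arrays of a single group, so a slide block, like slide 2 alone, sets the Nhp6 strains against wild type replicate 3 alone and Hmo1-TAP replicate 1 alone against wild type replicate 3 or the Nhp6 strains, and replicate numbers do not pair arrays across strains. A random slide effect had a correlation from -0.07 to -0.05. Depth was not limiting in most spots, but input signal on wild type replicate 1 and Hmo1-TAP replicate 3 was low, 80 tested probes had dim pull-down on all 3 arrays of a group, and 98 probes were left out. Promoter windows of 300 bp and windows without other coding sequence were not run, since probes were assigned by the array's labels.

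With the slide block, calls against wild type fell to 0 probes, 5 promoters, 0 coding regions and 3 upstream ends in Nhp6A-TAP, to 0 probes, 0 coding regions and 0 upstream ends in Nhp6B-TAP, and to 12, 21, 0 and 11 in Hmo1-TAP, with 1 promoter left for Hmo1-TAP against Nhp6A-TAP and 15 against Nhp6B-TAP. Within slide 2 alone they were 13, 11, 2 and 40 in Nhp6A-TAP, 0 probes, 0 coding regions and 0 upstream ends in Nhp6B-TAP, 52 probes, 21 promoters and 0 coding regions in Hmo1-TAP, and 20 and 15 promoters in the direct comparisons. A random slide effect gave 638 probes and 189 promoters in Nhp6A-TAP, and 13 probes, 8 promoters and 3 coding regions in Nhp6B-TAP. Normexp background correction gave 1092 probes, 221 coding regions and 254 upstream ends in Nhp6A-TAP, and 4 probes and 0 coding regions in Nhp6B-TAP. Loess gave 222 coding regions in Nhp6A-TAP, 2 probes, 0 coding regions and 4 upstream ends in Nhp6B-TAP, 83 probes and 15 coding regions in Hmo1-TAP, 34 and 13 promoters in the direct comparisons, and profile correlations of 0.66, 0.57 and 0.64. Centring on the half-sample mode gave 219 probes, 53 promoters, 29 coding regions and 73 upstream ends in Nhp6A-TAP, 4 upstream ends in Nhp6B-TAP and 37 promoters for Hmo1-TAP against Nhp6A-TAP. Scaling by the median absolute deviation gave 576 probes in Nhp6A-TAP, and 24 probes, 7 promoters, 2 coding regions and 26 upstream ends in Nhp6B-TAP. The deposited log2 values gave 18 probes and 6 promoters in Nhp6B-TAP. The pull-down channel alone gave 910 probes, 275 promoters and 192 coding regions in Nhp6A-TAP, 37 probes, 46 promoters, 22 coding regions and 43 upstream ends in Nhp6B-TAP, 31 upstream ends in Hmo1-TAP and 167 promoters for Hmo1-TAP against Nhp6A-TAP. A fit of only the 2 groups compared gave 220 probes and 50 coding regions in Nhp6A-TAP, and 3 probes and 0 coding regions in Nhp6B-TAP. With both dim-input arrays left out there were 34 coding regions in Nhp6A-TAP, and 1 promoter, 0 coding regions and 11 upstream ends in Nhp6B-TAP. The GC correction gave 2 and the replicate block 0 coding regions in Nhp6B-TAP, and the replicate block 4 bound regions in Nhp6A-TAP. Without their upstream 300 bp, 39 coding regions were called in Nhp6A-TAP, 3 in Nhp6B-TAP and 9 in Hmo1-TAP. With runs of 2 probes 70 regions were bound in Nhp6A-TAP and 54 in Hmo1-TAP. Of the 12 lists that camera called in promoters and coding regions, 3 were called with an estimated correlation. Fry, which tests against no change and not against other genes, called 22 of all 129 tests. An estimated correlation ended the ribosomal-protein calls in promoters (0.85 in Nhp6A-TAP and 0.49 in Nhp6B-TAP), in coding regions (0.17 in Nhp6B-TAP) and at upstream ends (0.67 and 0.46).

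With each array left out in turn, the lowest and highest counts in Nhp6A-TAP were 128 and 362 probes, 65 and 160 promoters, 26 and 70 coding regions, 79 and 200 upstream ends, and 0 and 15 bound regions. In Nhp6B-TAP they were 1 and 7 probes, 0 and 1 promoters, 0 and 2 coding regions, 0 and 24 upstream ends, and 0 and 0 bound regions, and in Hmo1-TAP 129 and 142 probes, 32 and 39 promoters, 18 and 24 coding regions, 18 and 22 upstream ends, and 17 and 25 bound regions. Between strains 0 and 1 promoters were called for Nhp6A-TAP against Nhp6B-TAP, 46 and 73 for Hmo1-TAP against Nhp6A-TAP, and 22 and 34 for Hmo1-TAP against Nhp6B-TAP. Called lists ranged from 11 to 15. The ribosomal-protein median ranged, in Nhp6A-TAP, from 0.73 to 0.99 in promoters, 0.35 to 0.46 in coding regions and 0.58 to 0.78 at upstream ends, in Nhp6B-TAP from 0.39 to 0.62, 0.12 to 0.2 and 0.38 to 0.57, and in Hmo1-TAP from 0.7 to 0.96, 0.18 to 0.31 and 0.44 to 0.74. Profile correlations ranged from 0.63 to 0.78 for Nhp6A-TAP and Nhp6B-TAP, 0.41 to 0.6 for Nhp6A-TAP and Hmo1-TAP, and 0.42 to 0.64 for Nhp6B-TAP and Hmo1-TAP.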

Other observations

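Beyond the groups above, promoters of the phosphate regulon stood high in Nhp6A-TAP, with a median of 0.81 over 8 members, 2 of them called, ARB1/PHM8 (1.22) and PHO84/GTR1 (1.15), the latter with the gene of the high-affinity phosphate transporter, and 5 when adjusted over the list alone (camera adjusted p = 0.064). Mating and pheromone-response promoters had a median of 0.66 with 3 of 12 called and 6 when adjusted over the list alone (camera adjusted p = 0.064), amino acid biosynthesis promoters 0.49 with 7 of 26 called and 9 when adjusted over the list alone (0.17), and promoters of RNA polymerase I and III genes 0.41 with 2 of 16 called, RPC40/DBF20 (2) and CPR1/RPA14 (1.19), and 5 when adjusted over the list alone (0.82). Ribosome biogenesis promoters had a median of 0.44 with 3 of 45 called in both ways (0.81), and heat shock promoters 0.56 with 2 of 10 called and 4 when adjusted over the list alone (0.53). None of these lists was called against other promoters. Fry gave adjusted p values under 0.05 for 11 of 21 promoter lists in Nhp6A-TAP, 6 in Nhp6B-TAP and 1 in Hmo1-TAP.

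Median promoter differences in Nhp6A-TAP of the remaining lists, each without a camera call, were 0.25 for mitochondrial ribosomal proteins (2 of 35 called higher), 0.57 for translation factors (1 of 14), 0.62 for glycolysis (3 of 10, or 6 when adjusted over the list alone), 0.76 for core histones (0 of 6, but 5 when adjusted over the list alone), 0.54 for HMG-box proteins (0 of 5), 0.27 for oxidative phosphorylation (0 of 15), 0.41 for the TCA and glyoxylate cycle (0 of 7), 0.33 for meiosis and sporulation (1 of 23), 0.28 for subtelomeric families (1 of 18), 0.36 for ergosterol synthesis (1 of 9), 0.3 for iron and copper uptake (2 of 9), 0.57 for cell wall genes (2 of 5), 0.44 for the proteasome (2 of 19, or 3 when adjusted over the list alone) and 0.49 for G1 cyclin and cell-cycle box genes (0 of 8). The other counts were the same when adjusted over each list alone. Galactose genes, with 8 coding regions and too few promoters, had a median of -0.23 in Nhp6A-TAP, -0.06 in Nhp6B-TAP and -0.07 in Hmo1-TAP, none called in limma, which gave 875, 319 and 269 coding regions of all kinds an unadjusted p under 0.05. The median over all promoters in Nhp6A-TAP was 0.34. Among HMG-box genes, the promoter of HMO1 was called in Hmo1-TAP (1.03), and the list medians were 0.48 in Nhp6B-TAP and 0.42 in Hmo1-TAP.

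Most ribosomal proteins of yeast are encoded by a pair of paralogous genes, and whether the copies of a pair share their Hmo1-TAP level was tested as a hypothesis set down before that result was seen. Over 59 pairs the Hmo1-TAP differences of the copies correlated at Pearson r = 0.23 (permutation p = 0.081, adjusted p = 0.16 over 2 relations tested) and Spearman rho = 0.17 (permutation p = 0.2), and r was 0.29 without the 2 pairs farthest from the median. For Nhp6A-TAP r was 0.17 (permutation p = 0.19, adjusted p = 0.19). In 12 pairs both copies exceeded 1.5, in 11 both lay under 0.5, and in 11 one exceeded 1.5 while the other lay under 0.5. The RPL13 and RPS16 pairs rest on the same promoters, RPS16B/RPL13A and RPL13B/RPS16A (3.14 and 2.28), yet were counted and permuted as separate pairs. RPL42 is among the split pairs (0.44 and 2.09), although a run of called probes under the RPL42A label had a mean of 3.15. These values leave the hypothesis undecided. Pairs are regions of the same arrays and not independent replicates.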
